A study of Mus musculus with 10 samples.

How the data were processed

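Hearts of C57BL/6 mice at 5 stages were measured by long RNA sequencing and by small RNA sequencing, with 1 library per stage and assay. Groups were taken from the sample titles. Per the labels' protocols, hearts were frozen and RNA was extracted with Trizol. The protocol given with the samples describes the small RNA preparation: RNA of 18 to 30 nucleotides was cut from a gel and ligated to 3' adapters that carry unique molecular identifiers. How the long RNA libraries were made, and whether they keep strand, is not given in the sources used here.

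The long RNA table holds FPKM values per locus, per the file headers. The table labels loci with assembly numbers and UCSC transcript identifiers and gives their positions. The build is mm9, per the submitters' processing notes, which also name HISAT, HISAT2, Bowtie, Bowtie2 and RSEM without versions or roles. Which of these made which table is not given in the sources used here. Of 35299 loci, 10578 share their interval with at least 1 other locus, so reads of overlapping loci may have been divided by the authors' quantification, and 8534 carry no transcript identifier. The identifiers were looked up in both name tables used here, 0 loci matched, and no coordinate was converted, because the reference table describes another assembly (GRCm38.p6). For that reason the gene lists fixed for long RNA, the pairs of miRNAs with host genes, the search for miRNA seed sites, and the values of Cmarr and Dtna are not analysed here.

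The small RNA table holds whole-number counts per mature miRNA, as deposited, although its name carries the word FPKM. Its columns sum to different totals, between 10479309 and 12953867. Whether reads or molecular identifiers were counted, and how reads shared by near-identical miRNAs such as the let-7 members or the paralogous miR-17 clusters were assigned, is not given in the sources used here, so members of such families are uncertain individually. The design had assumed a scaled unit for this table. Since it holds counts, they were divided by the library total to give counts per 1000000 (CPM) for the main values, the low-value filter of 10 was applied to counts, and the counts as deposited became the alternative scaling. A count test needs replicates and was not run.

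Differences were taken as log2(value + 1), which understates the differences of low features. A miRNA was compared where either stage had at least 10 counts, and a locus where either stage had at least 1 FPKM. Features with a difference of at least 1 on this scale (2-fold) were called higher or lower. This is a rule of size and not a test, and no p-value is given. Comparisons were E14.5 with E10.5, E17.5 with E14.5, the newborn with E17.5, the adult with the newborn, and the adult with E10.5. For single miRNAs, ratios of CPM carry exact Clopper-Pearson 95% intervals conditional on the sum of both counts. A count of 0 allows up to 3 counts, which is 0.286 CPM at E10.5 and 0.232 CPM in the adult. These intervals and floors cover counting error only.

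For each miRNA list the median log2 difference was given with its 95% order-statistic interval, or the range for fewer than 6 members, and with its percentile among 10000 random lists of the same size matched on mean abundance in 20 bins (2000 lists for loci). The percentile describes these libraries. Members of a list can be arms of the same hairpin or lie in the same cluster, while the interval and the percentile treat them as independent. Neither measures a spread between animals. The lists, the comparisons, the size limits and the alternatives marked as planned were fixed before the data were examined. The Dlk1-Dio3 list was checked against the reference table's names: 55 of its 57 hairpin names were found, all 55 on chromosome 12.

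The text names miR-540-3p, the 10 miRNAs with the largest differences in each direction for both adult comparisons and the 5 largest for the other steps among those with at least 100 counts in either stage, and up to 4 members of each list. For loci, 2 identifiers per direction with at least 10 FPKM are named. miR-208a-3p and miR-128-3p, the miRNAs of the epithelial, miR-34 with miR-449 and miR-183 lists and the hairpin clusters were chosen after their values were seen. The neural list was written after miR-9 had been seen and before the values of its members were.

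Other settings were tried: pseudocounts of 0.1 and 5, no filter or one 10 times as high, a 4-fold limit, scaling by the median ratio to the geometric mean, scaling to the same total, the 10 most abundant miRNAs left out and the mitochondrial loci left out. Leaving out the Dlk1-Dio3 miRNAs, miR-1a-3p, the locus at 5711970 FPKM or the newborn library was added after seeing the data. Long RNA depth is not stated in the table. Relative depth was read from loci under 0.05 FPKM, whose ratios to E17.5 gather at the value of 1 fragment: within 0.05 log2 units of that ratio or of its 2-fold steps lay 69.7% of such loci at E10.5 and 70.3% in the adult.

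The size rule was tested on simulated counts with 200 miRNAs altered by known folds. For the adult against E10.5, with 772 miRNAs compared, a 4-fold alteration was called for 93 of 100 raised and 90 of 100 lowered miRNAs and for all 69 of 69 altered ones with at least 1000 counts, and 1 unaltered miRNA was called. A 2.5-fold alteration was called for 77 and 67 of 100 each, with 795 compared. The simulated counts carried counting error only, without a spread between animals or libraries, and as many miRNAs were raised as lowered. The low number of unaltered miRNAs called was thus largely set by construction. How often the rule calls miRNAs because of animal, library or scaling differences was not tested. For the list percentile, 8 of 200 random lists of 12 miRNAs fell outside the central 95%, and 50 of 50 lists raised by 3 log2 units lay above it. These random lists came from the same miRNAs that define the percentile, so their share outside was largely set by construction. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.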

Results

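The series followed the mouse heart from mid-gestation to adulthood. Whole hearts of C57BL/6 mice were taken at embryonic days 10.5, 14.5 and 17.5 (E10.5, E14.5, E17.5), in the newborn and in the adult. Each of the 5 stages gave 1 long RNA library and 1 small RNA library, 10 libraries in all. The labels name cardiomyocytes as the cell type and heart tissue as the source, so the values below are described as those of heart tissue. With 1 library per stage and assay there was no replicate spread, no difference between stages was tested, and "higher" and "lower" below describe these libraries. The small RNA table listed 1908 mature miRNAs, of which 800 had at least 10 counts in at least 1 library, and the long RNA table listed 35299 loci, of which 15102 reached 1 FPKM in at least 1 library. Total miRNA counts were 10479309 at E10.5, 11526413 at E14.5, 12848794 at E17.5, 12732634 in the newborn and 12953867 in the adult. Intervals on ratios of counts are 95% exact Clopper-Pearson intervals and cover counting error only.

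The series title names miR-540-3p together with the long non-coding RNA Cmarr and with Dtna, which encodes alpha-dystrobrevin of the dystrophin-associated complex. miR-540-3p was lower at each later stage. It had 1955 counts at E10.5, 694 at E14.5, 484 at E17.5, 202 in the newborn and 19 in the adult. Scaled to the library total, as counts per 1000000 (CPM), this was 187, 60.2, 37.7, 15.9 and 1.47. The E10.5 value was 127-fold the adult value (81.2 to 212), and the newborn value was 10.8-fold the adult value (6.75 to 18.3). Between neighbouring embryonic stages the ratios were smaller, at 3.10 (2.84 to 3.38) from E10.5 to E14.5 and 1.60 (1.42 to 1.80) from E14.5 to E17.5. All these ratios are in CPM, and their size depends on the scaling. The log2 difference of miR-540-3p in the adult from E10.5 was -6.25 in CPM and -4.23 under median-ratio scaling. From the newborn it was -1.93 under median-ratio scaling. The other arm of the hairpin, miR-540-5p, had 10 counts at E10.5, 1 at E14.5, 1 at E17.5 and 0 in the newborn and the adult. The long RNA values of Cmarr and Dtna are not analysed here, because the table carries locus and transcript identifiers that none of the name tables used here pairs with symbols.

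miR-540 lies in the imprinted Dlk1-Dio3 domain, whose maternally expressed miRNAs form a large cluster on chromosome 12. Of its 90 measured members, 88 were at least 2-fold lower in the adult than at E10.5, 2 were in neither class and 0 were higher. The median log2 difference was -5.03 (95% interval -5.56 to -4.35), and 0 of 10000 random lists matched on mean abundance had a median as low. Because 16 members had no count in the adult, the median was also taken with those members at 3 counts, without a pseudocount, and was then -5.84. At E10.5 the cluster held 10.3% of all miRNA counts, against 2.51% in the newborn and 0.225% in the adult. The largest differences were those of miR-323-3p, at 2351 CPM at E10.5 and 5.71 in the adult, and of miR-370-3p, at 6907 and 21.4 CPM. miR-433-3p (7109 and 39.1 CPM) and miR-758-3p (156 and 0.0772 CPM) followed. The adult value of miR-758-3p was under the floor of 0.232 CPM, so the size of its difference depends on the pseudocount. Within the cluster miR-540-3p ranked 20 of 90 by the size of its log2 difference of -6.25. Of the 90 members, 70 were lower at all 4 steps (77.8%), against 211 of the 710 other measured miRNAs (29.7%). Under median-ratio scaling these counts were 54 (60.0%) and 51 (7.18%), and 79 members were at least 2-fold lower in the adult than at E10.5 (median -3.02).

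**Figure D1:**
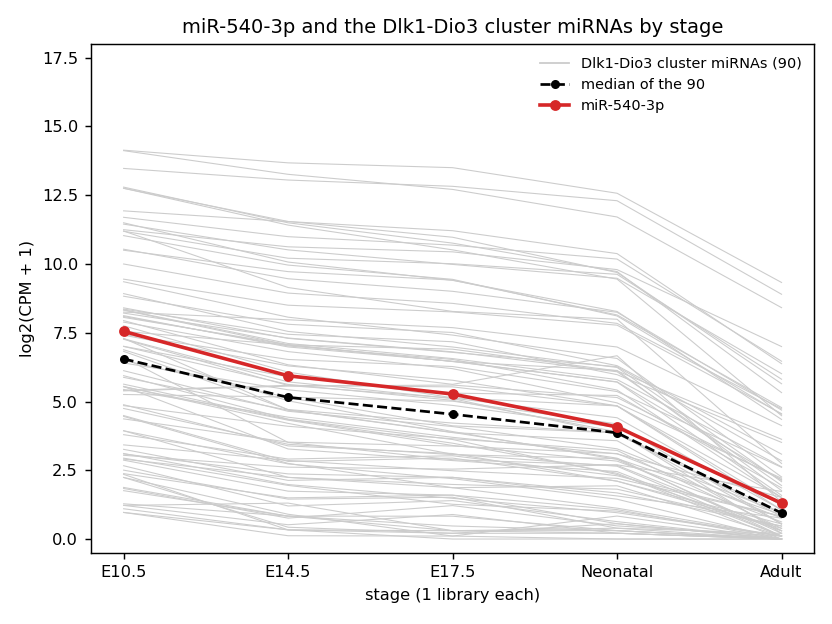
Abundance of the 90 measured Dlk1-Dio3 cluster miRNAs (grey lines), their median (dashed line) and miR-540-3p (red line) as log2(CPM + 1) on the y axis, in the 1 small RNA library of each stage on the x axis. miR-540-3p went from 187 CPM at E10.5 to 1.47 CPM in the adult, and the cluster's median log2 difference between these stages was -5.03.

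The comparison of the adult with E10.5 spans the whole series. Beside the Dlk1-Dio3 cluster, the miRNAs with the largest lower values in the adult included miR-335-3p, from an intron of the imprinted gene Mest (40031 CPM at E10.5, 195 in the adult), and both arms of miR-483, from an intron of Igf2 (miR-483-3p, 495 and 1.62 CPM, and miR-483-5p, 1484 and 7.80 CPM). The pluripotency-associated miR-302b-3p was at 179 CPM at E10.5 and 0.154 in the adult, which is under the floor of 0.232 CPM, so the size of its difference depends on the pseudocount. miR-134-5p (log2 difference -7.15) and miR-409-3p (-7.11) of the Dlk1-Dio3 cluster completed the 10 lowest. The largest higher values were those of let-7b-5p (2011 and 27549 CPM, 13.7-fold, 13.5 to 13.9), let-7j (log2 difference 3.41), miR-146a-5p (85.2 and 842 CPM), miR-881-3p (0.954 and 16.6 CPM), miR-871-3p (3.14), miR-29a-3p (77.4 and 688 CPM), miR-195a-5p (9.92 and 86.6 CPM), miR-150-5p (12.8 and 101 CPM), let-7k (2.87) and miR-22-5p (2.83).

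Muscle miRNAs made up 7.76% of counts at E10.5 and 28.4% in the adult. Of the 10 measured, 4 were higher, 2 lower and 4 in neither class, with a median log2 difference of 0.70 (-2.12 to 1.20) at percentile 98.4 of matched random lists. Under median-ratio scaling 8 were higher and 1 lower, with a median of 3.08. miR-1a-3p, the main muscle miRNA, had 42165 CPM at E10.5 and 224767 in the adult (5.33-fold, 5.31 to 5.35) and alone took 22.5% of the adult library (Wilson 95% interval within 0.1 points of this share). The pair encoded in introns of the cardiac myosin heavy chain genes diverged: miR-208b-3p, from the gene of the fetal beta form, was at 704 CPM at E10.5 and 24.3 in the adult, while miR-208a-3p, from the gene of the adult alpha form, was at 229 and 395 CPM. miR-206-3p, best known from skeletal muscle, was at 363 and 82.8 CPM, a lower value that turned into a log2 difference of 0.25 under median-ratio scaling, and miR-486-5p was at 3892 and 8967 CPM. miR-133a-3p (log2 difference 1.09) and miR-133b-3p (1.01), which are nearly identical in sequence, were the other higher members.

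The let-7 and miR-98 family, which accumulates as tissues differentiate, had 6 of 9 members higher and 1 lower, with a median of 1.65 (0.43 to 2.61, percentile 99.9), and 8 higher and 0 lower under median-ratio scaling (median 4.03). let-7f-5p (log2 difference 2.61) and let-7d-5p (2.37) followed let-7b-5p. let-7e-5p went against the family, at -1.96, and that sign turned to 0.42 under median-ratio scaling. All 3 members of the miR-29 family, which targets collagen transcripts, were higher, with a median of 2.57 and a range from 2.22 (miR-29b-3p) to 3.14 (miR-29a-3p), percentile 100. The family's median was 1.52 with a pseudocount of 5 and 4.14 under median-ratio scaling. By contrast all 13 members of the miR-17-92 and paralogous clusters, known for promoting proliferation, were lower, with a median of -3.51 (-4.83 to -2.40, percentile 9.71), and 9 lower under median-ratio scaling (median -1.86). miR-18a-5p (-5.36), miR-17-5p (2361 and 66.6 CPM), miR-363-3p (-4.83) and miR-20a-5p (-4.53) had the largest differences. All 8 measured members of the miR-302 and miR-290 clusters were lower, with a median of -3.39 and 0 of 10000 random lists as low, and 7 were lower under median-ratio scaling (median -2.33).

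Lists that stand for other cell types differed among themselves. Of 8 miRNAs of fibroblasts and smooth muscle, 6 were lower and 0 higher, among them miR-199a-5p (13991 and 1504 CPM), miR-21a-5p (34680 and 5450 CPM) and miR-199b-5p (-2.43), and the list's median of -1.86 (percentile 30.2) turned to 0.51 under median-ratio scaling, with miR-199a-3p (-1.98) turning to 0.40, miR-214-3p (-1.74) to 0.61 and miR-145a-5p (-1.39) to 0.94. Of 5 endothelial miRNAs, 1 was higher and 1 lower, with a median of 0.81 at percentile 99.0, against 4 higher and 0 lower with a median of 3.18 under median-ratio scaling. miR-221-3p had a log2 difference of 1.65, miR-126a-3p one of 0.82 and miR-130a-3p one of -2.07, which turned to 0.26 under median-ratio scaling. Of 6 blood cell miRNAs, 2 were higher, miR-150-5p of lymphocytes (2.89) and miR-144-3p of erythroid cells (1.18), with a list median of 0.58 at percentile 99.4, and all 6 were higher under median-ratio scaling (median 2.89). The miR-15 family had 1 member higher, miR-195a-5p (3.00), and 2 lower, miR-322-5p (-2.82) and miR-15b-5p (-2.07, which turned to 0.13 under median-ratio scaling), with a median of -0.62 at percentile 85.9 that turned to 1.44 under median-ratio scaling. None of the 5 miR-30 members reached the 2-fold limit in CPM (median 0.27, percentile 76.2), while all 5 were higher under median-ratio scaling (median 2.65). miRNAs typical of other organs were mostly lower, 7 of 11, with a median of -3.53 at percentile 13.2 (4 higher, 6 lower and a median of -1.17 under median-ratio scaling), led by miR-200b-3p (-6.50), miR-205-5p (-6.49), miR-200a-3p (-4.98) and miR-122-5p (-4.70).

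Over all 765 miRNAs compared between the adult and E10.5, 61 were higher and 522 lower, and the median log2 difference of all was -1.59 (-1.74 to -1.45). This shift depends on the scaling. Under median-ratio scaling the split was 190 higher and 245 lower and the median was -0.38, so the values of single miRNAs and lists are best read against the shift. Relative to the median of all 800 measured miRNAs, the Dlk1-Dio3 list stood at -3.53, the muscle list at 2.20, the let-7 and miR-98 list at 3.15 and the miR-29 list at 4.07. The shift also differed with abundance. Random lists matched on mean abundance had medians of -1.95, -1.43, 0.11 and -1.88 for these lists in the same order. Against miRNAs of like abundance the let-7 and miR-98 list, with its median of 1.65, thus stood out less than the 3.15 implies.

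**Figure D2:**
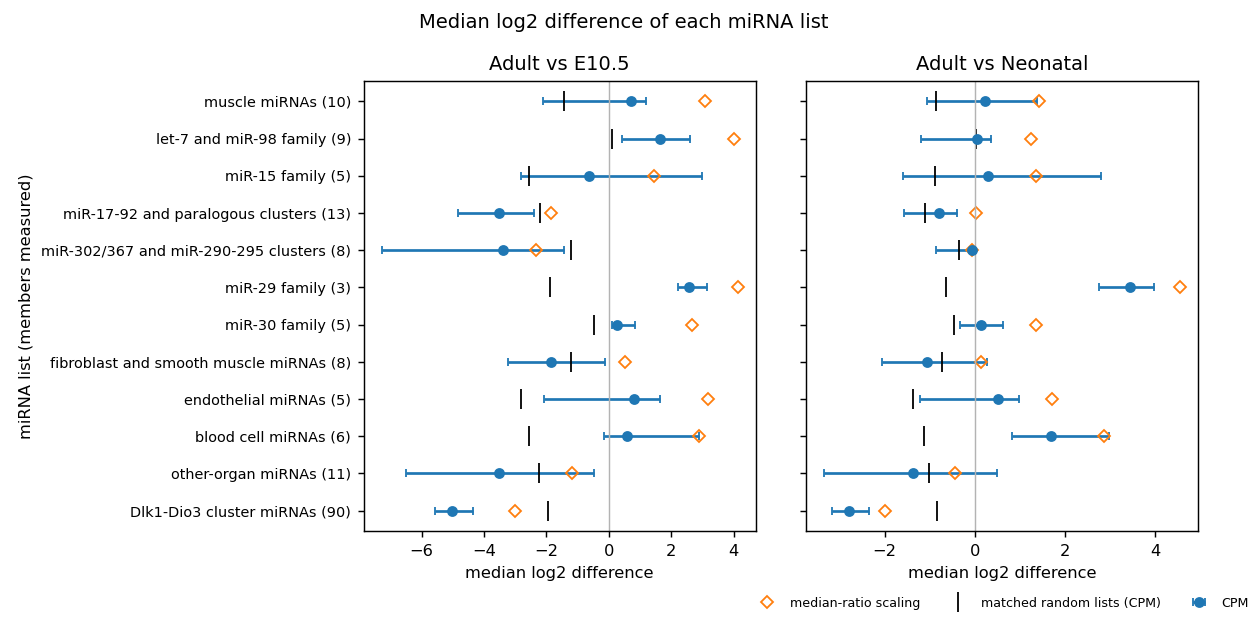
Median log2 difference (x axis) of each fixed miRNA list (y axis, members measured in brackets) for the adult against E10.5 and against the newborn. Blue points are medians in CPM with their 95% order-statistic intervals (the range for lists under 6 members), open diamonds the medians under median-ratio scaling and black bars the medians of matched random lists. The Dlk1-Dio3 cluster is lowest in both panels, at -5.03 and -2.79 in CPM, and the miR-29 family highest, at 2.57 and 3.44. With a pseudocount of 5 the let-7 and miR-98 family, at 1.65, stood above the miR-29 family for the adult against E10.5.

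The adult and the newborn bracket the maturation transition named in the title. The Dlk1-Dio3 cluster had 71 of 90 members lower and 0 higher, with a median of -2.79 (-3.17 to -2.35) and 0 of 10000 random lists as low, and 65 were lower under median-ratio scaling. miR-770-3p (100 and 1.54 CPM), miR-323-3p (253 and 5.71 CPM) and miR-370-3p (699 and 21.4 CPM) were among the 10 lowest miRNAs of the step. miR-208b-3p was at 831 CPM in the newborn and 24.3 in the adult, 34.2-fold lower (30.5 to 38.3), while miR-1a-3p was 2.61-fold higher in the adult and miR-486-5p had a log2 difference of 1.50. The muscle list as a whole had 2 higher, 2 lower and 6 in neither class (median 0.23, percentile 96.4), or 7 higher and 1 lower under median-ratio scaling (median 1.43), and its other lower member, miR-206-3p at -1.07, turned to 0.13 under median-ratio scaling. The miR-29 family summed to 81.2 CPM at E10.5, 39.4 at E14.5, 37.4 at E17.5, 44.0 in the newborn and 715 in the adult. miR-29a-3p was 16.1-fold higher (14.8 to 17.6), miR-29b-3p had a log2 difference of 3.44 and miR-29c-3p one of 2.75, and the family's median of 3.44 was 2.01 with a pseudocount of 5 and 4.55 under median-ratio scaling. Among blood cell miRNAs 5 of 6 were higher (median 1.68, percentile 100), with miR-150-5p at 2.97, miR-144-3p at 2.03, miR-155-5p at 1.73 and miR-451a at 1.63.

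Other miRNAs with large higher values in the adult than in the newborn were miR-881-3p (3.51), miR-871-3p (3.20), miR-465b-5p (3.02), miR-195a-5p (2.80), miR-22-5p (2.33) and miR-146a-5p (2.15). Lower were miR-3099-3p (92.2 and 0.695 CPM), miR-483-5p (-5.20), miR-6540-5p (-4.98) and miR-215-5p (1565 and 55.7 CPM). Both arms of the neural miR-9 were also among the 10 lowest, miR-9-3p at -5.19 and miR-9-5p at -4.87, because they were high in the newborn library alone. The let-7 and miR-98 family had a median of 0.05 (percentile 59.1) in CPM and of 1.25 under median-ratio scaling, where 6 of 9 were higher and 0 lower. In CPM 0 were higher, with let-7e-5p (-1.59) and let-7i-5p (-1.19, 0.02 under median-ratio scaling) lower. The fibroblast and smooth muscle list had 5 of 8 lower (median -1.06, percentile 32.4, turning to 0.13 under median-ratio scaling, as did miR-199a-3p to 0.18 and miR-199b-5p to 0.08). For the remaining lists the medians were 0.28 for the miR-15 family (1.35 under median-ratio scaling), -0.80 for the miR-17-92 and paralogous clusters (0.03 under median-ratio scaling), -0.05 for the miR-302 and miR-290 clusters, 0.14 for the miR-30 family (1.35, with 4 of 5 higher), 0.52 for the endothelial (1.72, with 4 of 5 higher) and -1.37 for the other-organ miRNAs (-0.44, with 2 higher and 2 lower). In all, 43 of 636 miRNAs were higher and 275 lower, with a median of -0.85, and the split under median-ratio scaling was 149 and 176 with a median of -0.17.

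**Figure D3:**
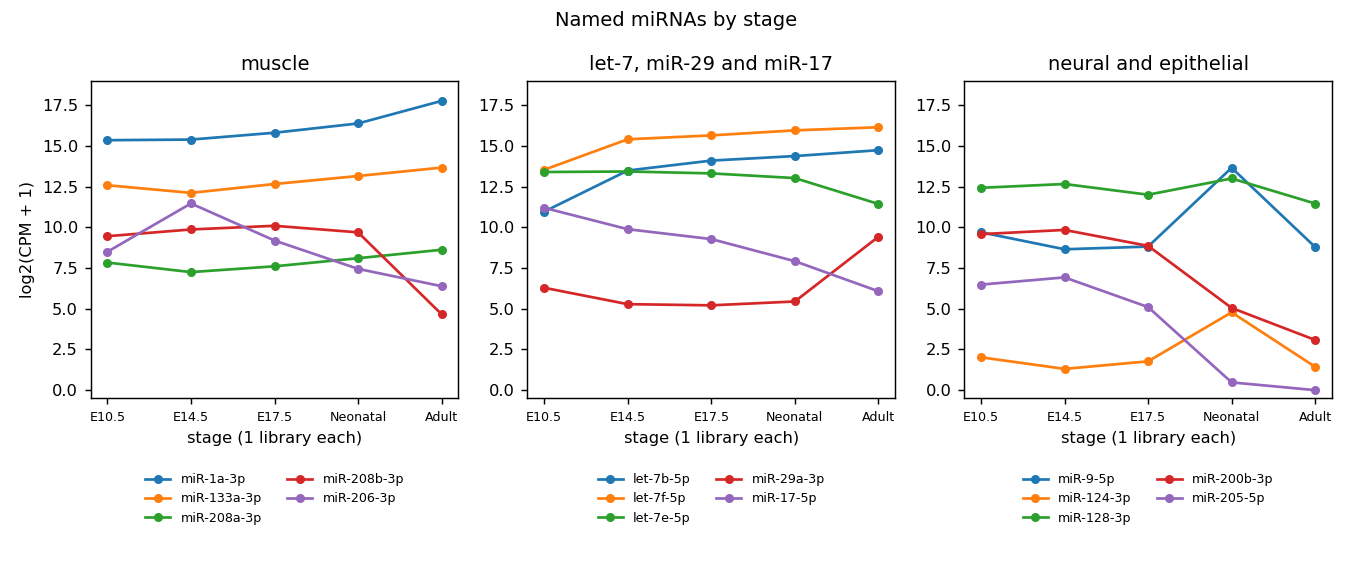
Abundance of named miRNAs as log2(CPM + 1) on the y axis, in the 1 small RNA library of each stage on the x axis, for muscle miRNAs, for let-7, miR-29 and miR-17 members, and for neural and epithelial miRNAs. miR-208b-3p and miR-29a-3p differ mainly between newborn and adult, and miR-9-5p is at 13011 CPM in the newborn against 452 at E17.5 and 443 in the adult.

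The step from E10.5 to E14.5 separated the looping, early chambered heart from the septated heart. The pluripotency-associated clusters were nearly lost: miR-302b-3p was at 179 and 8.50 CPM, 21.1-fold lower (17.2 to 26.1), followed by miR-302a-5p (-3.91), miR-292-5p (-3.87), miR-302d-3p (-3.19) and miR-302a-3p (-3.13), and all 8 measured members of the list were lower (median -2.74, 0 of 10000 random lists as low). The let-7 and miR-98 family had 7 of 9 members higher, with a median of 1.72 (0.98 to 1.94, percentile 100), and let-7j (3.48) and let-7b-5p (2.52) were among the 5 highest miRNAs. miR-449a-3p (3.37) and miR-449a-5p (2.82), known from ciliated epithelia, and miR-206-3p (363 and 2848 CPM, 7.85-fold, 7.59 to 8.12) completed these 5. The Dlk1-Dio3 cluster had 54 of 90 lower and 0 higher (median -1.08), but 8 lower under median-ratio scaling (median -0.41). Of the miR-17-92 and paralogous clusters 7 of 13 members were lower (median -1.02, percentile 2.82), but 1 under median-ratio scaling (median -0.32). Muscle miRNAs had a median of -0.22 (0.48 under median-ratio scaling), with miR-206-3p alone of 10 past the 2-fold limit in CPM and 3 higher under median-ratio scaling. Of 763 miRNAs, 22 were higher and 213 lower with a median of -0.64. Under median-ratio scaling 52 were higher and 34 lower, so the excess of lower values rests on the scaling.

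From E14.5 to E17.5, within fetal growth, fewer miRNAs differed: 7 of 679 were higher and 38 lower, with a median of -0.20, or 7 and 20 under median-ratio scaling. miR-122-5p, the main liver miRNA, was at 118 and 619 CPM (5.22-fold, 4.93 to 5.54), but had been at 894 CPM at E10.5. miR-449a-5p (2.31), miR-92b-3p (1.67), miR-92b-5p (1.67) and miR-338-5p (0.96, under the 2-fold limit) followed. Lowest were miR-128-2-5p (-3.49), miR-363-3p (55.4 and 6.38 CPM), miR-20b-5p (-2.56), miR-3963 (-2.36) and miR-690 (-2.31). miR-363-3p and miR-20b-5p belong to the miR-106a-363 cluster on the X chromosome, and the miR-17-92 list with its paralogues had 4 of 13 members lower (median -0.61, percentile 0.275). The muscle list had a median of 0.41 (0.22 to 0.54) with 0 of 10000 random lists as high, although 0 of its 10 members reached the 2-fold limit upward and 1, miR-206-3p (-2.28), reached it downward. The Dlk1-Dio3 cluster had 4 of 90 lower and a median of -0.48, or 0 lower and -0.24 under median-ratio scaling.

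Birth lies between the E17.5 and newborn samples. miR-9-3p (13.3 and 567 CPM) and miR-9-5p (452 and 13011 CPM), miRNAs of neural cells, were the highest of this step, followed by miR-135a-1-3p (3.62), miR-1298-5p (3.60) and the neuronal miR-124-3p (2.41 and 26.5 CPM). Lowest were miR-449a-5p (104 and 1.96 CPM, 53.0-fold, 35.7 to 82.2) and 4 miRNAs of epithelial cells, miR-205-5p (33.5 and 0.393 CPM), miR-200b-3p (467 and 32.2 CPM), miR-200a-3p (-3.28) and miR-429-3p (-3.26). The other-organ list held both kinds, with 2 members higher and 7 of 11 lower (median -2.55, 0 of 10000 random lists as low). Muscle miRNAs had a median of 0.29 (percentile 100) with miR-206-3p at -1.74, and the Dlk1-Dio3 cluster had 20 of 90 lower, 1 higher, miR-770-3p at 1.04, and a median of -0.70 (-0.75 to -0.52), with 6 lower and a median of -0.49 under median-ratio scaling. Of 673 miRNAs, 34 were higher and 64 lower (median -0.23), and 36 and 36 under median-ratio scaling.

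Over the 4 steps, 275 of 800 miRNAs were lower at every step and 17 higher at every step, with at least a 2-fold total difference. Without the limit on the total difference, a random order of 5 values gives 0.833% per direction, or 6.67 miRNAs, and with it no more than that. Under median-ratio scaling the counts were 96 lower and 98 higher. The Spearman correlation across miRNAs was 0.757 between the E10.5 and adult libraries and 0.870 between the newborn and the adult. The corresponding values across long RNA loci were 0.745 and 0.878. Features are not independent replicates, so these values describe the similarity of the libraries.

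In the long RNA libraries, the loci could be followed by position and identifier only. The 8 loci on the mitochondrial chromosome, which encode subunits of the respiratory chain and ribosomal RNAs, were all at least 2-fold higher in the adult than at E10.5, with a median log2 difference of 3.14 (2.39 to 3.43) and 0 of 2000 matched random lists as high. Their summed value was 3215 FPKM at E10.5, 3214 at E14.5, 4938 at E17.5, 10538 in the newborn and 33663 in the adult. Most of this sum came from 1 locus (XLOC_034014), at 2799 FPKM at E10.5 and 30097 in the adult. All 8 were higher in the step from newborn to adult (median 1.62), 1 of 8 in the step across birth (median 0.61), 2 of 8 from E14.5 to E17.5 (median 0.85) and 0 of 8 from E10.5 to E14.5 (median -0.01). The summed value of the 18 loci on the Y chromosome was 68.3 FPKM at E10.5, 25.4 at E14.5, 56.5 at E17.5, 0.294 in the newborn and 0.0903 in the adult. Y-linked loci were thus measured in the 3 embryonic long RNA libraries and were near 0 in both later ones. In the long RNA comparisons across birth and of the adult with E10.5, stage and Y-linked signal therefore differ together. A difference of sex cannot be told apart from one of stage there.

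Of the loci compared between the adult and E10.5, 3095 were higher and 2543 lower of 14241. The locus with the largest higher value (XLOC_008373, transcript uc007rkc.1, chromosome 13, 91992991 to 92016490 in mm9) was at 4.65 FPKM at E10.5 and 1967 in the adult, and the next (XLOC_030302, uc009kzm.1, chromosome 8, 15041446 to 15133541) at 0.542 and 485 FPKM. At the other end XLOC_029503 (uc009iut.1, chromosome 7, 111000267 to 111001721) was at 29718 and 5.97 FPKM. A further locus (XLOC_014152, uc008drq.1, chromosome 17, 81772444 to 82138966) was listed at 5711970 FPKM at E10.5 and between 290 and 785 at the other stages, so its E10.5 value stands outside the range of all other values and no difference is drawn from it. Loci without a transcript identifier leaned upward, with 479 of 1293 higher and 95 lower in the adult than at E10.5 (37.0% and 7.35%), against 18.9% and 17.7% of the 13809 loci with one. Loci entered this count by reaching 1 FPKM in any library. Of those without an identifier, 917 did so in the adult and 462 at E10.5, so the lean is partly set by the filter.

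The steps differed in size. From newborn to adult 1656 loci were higher and 1387 lower of 14081. Across birth 377 of 13509 were higher, 50.7% of those past the limit, from E14.5 to E17.5 228 and 206 of 13311, and from E10.5 to E14.5 660 and 260 of 13328. The median log2 difference of all loci lay between -0.04 and 0.04 in all 5 comparisons. The deposited FPKM values already had median-ratio factors close to 1, from 1.00 at E10.5 to 1.02 in the adult. A median near 0 may thus be set by their scaling and cannot show that long RNA lacked a shared shift. Of 15102 loci, 1190 were higher and 1277 lower at every step and at least 2-fold in total, where a random order gives at most 126 per direction. In the adult library 1 fragment is worth more: its depth, read from loci with few fragments, was 0.780 of that at E17.5, against 1.01 at E10.5, 1.05 at E14.5 and 1.00 in the newborn. Whether this affects the counts through low-abundance loci was not tested.

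**Figure D4:**
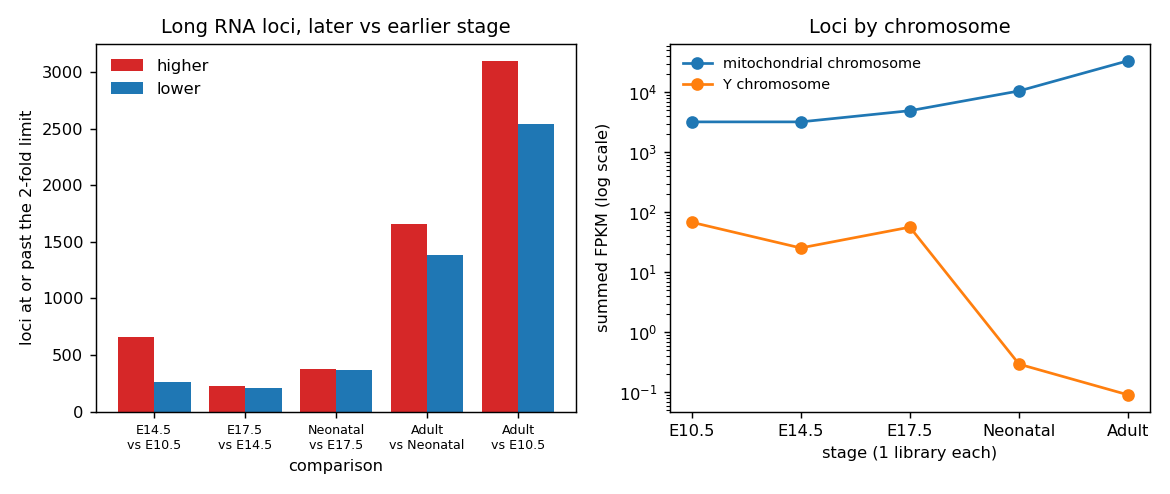
Left, number of long RNA loci (y axis) at least 2-fold higher (red) or lower (blue) in the later stage of each comparison (x axis). Right, FPKM summed over the 8 mitochondrial and the 18 Y chromosome loci on a log y axis, in the 1 long RNA library of each stage. The largest counts are those of the adult against E10.5, 3095 and 2543, and the mitochondrial sum is 33663 FPKM in the adult, of which 1 locus holds 30097.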

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

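With 1 library per stage, leaving out a replicate was not possible. No paired analysis was possible because each group has 1 library. Direction held for the Dlk1-Dio3 median and for miR-540-3p under all settings run. The settings that leave out the Dlk1-Dio3 miRNAs, miR-1a-3p, the extreme locus (alone or with the mitochondrial loci) or the newborn library were chosen after seeing the data. Counts of features follow the limits by construction, and otherwise the cause was not tested. Not run, for want of gene names: the exclusion of globin genes, sums per gene symbol, host gene pairs, seed sites and gene lists of long RNA. Of 1230 alternative values, 171 for counts and main results and 520 for other list medians and single miRNAs stayed within their interval or within 1.5 times. For counts and main results 117 moved further, where any change of a similarity counts as moved. Of the other list medians and single miRNAs 415 moved further and 7, all at least 2-fold in CPM, reversed. Among these 1230, 5 values under 2-fold in CPM changed sign: the miR-15 family median and its member miR-15a-5p for adult vs E10.5, each under median-ratio scaling (1.44) and without the 10 most abundant miRNAs (0.17), and the miR-17-92 median for adult vs newborn under median-ratio scaling (0.03). List medians outside this tally also changed sign under median-ratio scaling. Examples are the neural list for adult vs E10.5 (from -0.97 to 0.19) and the muscle list for E14.5 vs E10.5 (from -0.22 to 0.48). Loci near 1 fragment and miRNAs near 3 counts are at the detection limit.

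miRNAs higher and lower, in the order E14.5 vs E10.5, E17.5 vs E14.5, newborn vs E17.5, adult vs newborn and adult vs E10.5, moved by over 1.5 times as follows. Median-ratio scaling gave 52, 149 and 190 higher in the first comparison and both adult ones and 34, 20, 36, 176 and 245 lower in the 5. The 4-fold limit gave 6, 2, 11, 15 and 27 higher and 25, 9, 14, 148 and 313 lower. Counts as deposited gave 36, 24 and 56 higher in the first 3 and 65 and 117 lower in the E17.5 and newborn steps. A pseudocount of 0.1 gave 15 and 54 higher and 74 and 111 lower in the E17.5 and newborn steps. A pseudocount of 5 gave 4 and 15 higher in the E17.5 and newborn steps, and 111, 16 and 321 lower in the E14.5, E17.5 and last comparisons. The filter 10 times as high gave 4 and 17 higher in the E17.5 and newborn steps, and 137, 19 and 302 lower in the E14.5, E17.5 and last comparisons. Without the 10 most abundant miRNAs, 36, 52 and 117 were higher in the first, the birth step and the last and 137 lower in the first.

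For loci in the same order, the pseudocount of 0.1 gave 1054, 441 and 754 higher and 526, 410 and 669 lower in the first 3. A pseudocount of 5 gave 190, 79, 107, 766 and 1681 higher and 90, 51, 126, 492 and 1306 lower. The filter 10 times as high gave 211, 105, 150, 913 and 1792 higher and 113, 52, 173, 544 and 1430 lower, and the 4-fold limit 126, 36, 39, 370 and 1070 higher and 55, 49, 61, 342 and 822 lower. Scaling to the same total gave 12001 higher and 20 lower for E14.5 vs E10.5 and 11232 and 253 for adult vs E10.5, and with mitochondrial loci left out 12003 and 20, and 11361 and 246. The locus at 5711970 FPKM takes most of the E10.5 total. With it left out at the same total the counts were 689 and 233, and 3285 and 2357, and with the mitochondrial loci left out as well 691 and 234, and 3420 and 2272, all within 1.5 times.

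The Dlk1-Dio3 median for adult vs E10.5 was -5.77 and -3.82 with pseudocounts of 0.1 and 5, -5.57 under the higher filter and -3.02 under median-ratio scaling. For adult vs newborn it was -3.39, -1.69, -3.22 and -2.00, and -3.38 in counts as deposited. miR-540-3p was at -4.89 with a pseudocount of 5, -4.23 under median-ratio scaling, -5.81 without the 10 most abundant and -6.08 without miR-1a-3p for adult vs E10.5, and at -1.69, -1.93 and -2.67 (without miR-1a-3p) for adult vs newborn. Median-ratio scaling reversed the medians of fibroblast and smooth muscle miRNAs (0.51 and 0.13 in the adult comparisons) and, for adult vs E10.5, miR-206-3p (0.25), let-7e-5p (0.42), miR-15b-5p (0.13), miR-199a-3p (0.40) and miR-130a-3p (0.26). Over all miRNAs at least 2-fold different in CPM, the sign changed under median-ratio scaling for 93 in adult vs E10.5 and 13 in adult vs newborn, such as miR-214-3p (0.61) and let-7i-5p (0.02). In the main setting the fixed lists outside the central 95% of random lists from E14.5 to E17.5 were the muscle (percentile 100), miR-17-92 (0.275), miR-302 with miR-290 (0.41), other-organ (1.545) and Dlk1-Dio3 (0) lists. Such lists numbered 3 with a pseudocount of 5 and 3 under the higher filter. Monotonic counts became 98 higher and 96 lower miRNAs under median-ratio scaling, 2389 higher and 8 lower loci at the same total, 808 lower loci with a pseudocount of 5 and 1825 higher loci without the newborn library. As Pearson's r of log2 values and as Spearman's rho without a filter, E10.5 and adult similarity was 0.833 and 0.810 for miRNAs and 0.765 and 0.856 for loci, and newborn and adult similarity 0.927 and 0.850, and 0.897 and 0.898.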

Other observations

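Hairpins that neighbour each other in the reference table (GRCm38.p6, within 10 kb) formed 10 groups of at least 4 measured hairpins. These groups were formed after seeing the data and were not compared with random groups, and 522 of all 765 miRNAs were lower in the adult than at E10.5 in CPM. Among the low ones was the X-linked group of miR-322, miR-351, miR-450b, miR-503 and miR-542, with a median of -5.25 (-6.48 to -2.82) in the adult against E10.5, 9 of 10 mature miRNAs lower, and a median of -2.90 under median-ratio scaling. Its sum was 39117 CPM at E10.5, 11850 in the newborn and 595 in the adult, and miR-351-5p alone was at 29075 and 288 CPM. The parts of the Dlk1-Dio3 domain had medians of -5.14 (21 mature miRNAs) and -4.89 (63), or -2.86 and -3.04 under median-ratio scaling. The miR-302 group had a median of -4.93 (5 of 5 lower, -3.51 under median-ratio scaling), the group of miR-106a, miR-18b, miR-20b and miR-363 one of -3.72 (5 of 5) and the group of miR-291a to miR-295 one of -2.83 (7 of 7). Also lower were miR-188 to miR-532 on the X chromosome (median -3.29, 7 of 8 lower) and the miR-297, miR-466, miR-467 and miR-669 group on chromosome 2 (-1.88, 28 of 29 lower, and -0.71 under median-ratio scaling), the latter near the medians of all miRNAs, -1.59 and -0.38. The only group with a positive median in CPM was the X-linked one of miR-465, miR-470, miR-741, miR-871, miR-878 and miR-881, with 8 of 9 higher and a median of 2.04, from a sum of 5.53 CPM at E10.5 and 1.88 in the newborn to 63.1 in the adult. The group of miR-23b, miR-24-1 and miR-27b on chromosome 13 had a median of -0.28 and was above 0 under median-ratio scaling.

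Some hairpins differed in which arm was counted. The 5p arm of miR-27a took 40.4% of both arms' counts at E10.5 (Wilson 95% interval 39.4 to 41.3) and 2.34% in the adult (2.21 to 2.48). For miR-195a the 5p share was 15.7% (13.1 to 18.7) and 48.6% (46.6 to 50.6), and for miR-30b 31.3% (29.8 to 32.8) and 62.7% (61.2 to 64.2). Epithelial miRNAs, listed after seeing the data, were lower in the newborn than at E17.5 in 7 of 9 cases (median -2.80). The group of miR-183, miR-96 and miR-182 was lower already at E17.5 than at E14.5 (median -2.07), with a sum of 2557 CPM at E10.5, 2281 at E14.5, 533 at E17.5 and 66.4 in the adult. The list of miR-34 and miR-449 members had a median of 0.64 from E14.5 to E17.5 and of -1.76 across birth. miR-122-5p was at 894, 118, 619, 105 and 33.4 CPM in order of stage, and miR-206-3p at 363, 2848, 586, 174 and 82.8 CPM.

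The test of neural tissue as the source of the Dlk1-Dio3 miRNAs was chosen after the result was seen, and the other tests were set before, except the rescaling to the mean CPM of the other miRNAs, added after. The Dlk1-Dio3 miRNAs were lower in the adult than at E10.5. A few abundant miRNAs taking the counts is argued against as the whole cause: under median-ratio scaling, which left the smaller difference of both corrections, the cluster's median stayed at -3.02 (-3.33 to -2.54), and with the 10 most abundant miRNAs left out it was -4.61. Neural tissue as the source cannot be told apart from the heart itself: the cluster's median from E17.5 to the newborn was -0.70 (-0.75 to -0.52), but whether the newborn sample held more neural tissue is itself open. Between E10.5 and the adult the neural list had a median of -0.97 (-2.12 to -0.26, 5 of 12 lower, 0.19 under median-ratio scaling) and miR-9-5p was at 834 and 443 CPM, smaller differences than the cluster's -5.03, but several list members were near the floor at both stages and the heart's own level of the others is not known. Only neural tissue was weighed in this way, and tissue of other organs was not tested as a source. The other-organ list, which also holds neural members, had 7 of 11 lower and 0 higher in the adult than at E10.5 (median -3.53). Under median-ratio scaling 6 were lower and 4 higher (median -1.17). The stage of the heart, its makeup of cell types and the sex of the animals, on which 4 measured Y-linked loci near 0 in the newborn and adult long RNA libraries bear, stay open and untested with 1 library per stage.

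miR-9 was higher in the newborn library than at the stages before and after. The log2 difference of miR-9-5p from E17.5 was 4.84 in CPM and 5.07 (5.04 to 5.11) under median-ratio scaling. The choice between these scalings is thus argued against as the cause. Their outcome was largely settled in advance, because the median-ratio factors were close, at 1.16 for E17.5 and 0.982 for the newborn. A neural admixture in the newborn sample is a candidate explanation: 12 neural miRNAs not examined before exceeded the mean of E17.5 and the adult by a median of 1.19 (0.39 to 1.82), with 11 of 12 above 0 and 0 of 10000 random lists as high (random median 0.17). Low adult values add to this excess: against E17.5 alone the median was 0.80 with 4 of 12 at least 2-fold higher, miR-326-3p was at 18.0 CPM at E17.5 and 17.3 in the newborn, and miR-129-5p was higher at E10.5 (320 CPM) than in the newborn (193), as was miR-383-5p (36.1 and 27.1 CPM). Of the 12, 4 also reach 10 CPM in E17.5 or adult hearts (the most abundant, miR-128-3p, was at 4132 CPM at E17.5 and 8250 in the newborn), miR-124-3p reached only 26.5 CPM beside 13011 CPM of miR-9-5p, and the ratio of both in neural tissue was not measured here, so the origin of most of the miR-9 signal, a stage difference of the heart included, stays open and untested.

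Most miRNAs were lower in the adult than at E10.5. The 10 most abundant taking the counts is argued against as the whole cause: without them and with the rest rescaled to the same total, the median over the 755 others was -1.53 (-1.68 to -1.37), against -1.61 before. That rescaling also lowers the weight of the pseudocount, and with the total set to the mean CPM of the others, which keeps that weight, the median was -1.12 (-1.22 to -1.02), so part of the difference went with the 10. Median-ratio scaling centres the libraries by construction and cannot show whether the total amount of miRNA differed, which stays open and untested, as does the stage itself.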
